A study of Homo sapiens with 6 samples.

How the data were processed

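RNA sequencing of 6 libraries was analysed, 3 from cells with a non-silencing hairpin (NS) and 3 from cells with a hairpin against ACSS2 (shACSS2). Per the labels' protocols, RNA was extracted with a column kit, libraries were made with a SMARTER mRNA kit, and the cells were kept under puromycin after lentiviral infection. The sample tags and titles name ACSS2, and the groups here follow the titles. The titles write the knockdown as siACSS2, which would stand for an siRNA, while the treatment text describes a lentiviral hairpin and in 1 passage calls the line shNgBR. The hairpin of the treatment text is taken as the reagent here, and the conflict stays open. The sequence of the reagent is not given in the sources used here.

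The deposited table holds whole-number read counts per gene for each library, which the authors had not normalised. Per the submitters' processing notes, the tools named are fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 (given there as 4.3.1), with the build hg19. Read length, trimming settings, the treatment of reads that match several places and the strand setting of the counting are not given in the sources used here. All 58735 gene identifiers in the table were found in GENCODE v29, and 58708 of its names were identical to the names there. The other 27 had been turned into dates by spreadsheet software and were restored from the identifier. Since GENCODE v29 is an annotation of GRCh38 and the notes name hg19, the build of the alignment is open. The table holds no coordinates, and those printed are GENCODE v29 positions on GRCh38 found by gene identifier. Reads shared between overlapping genes, between a gene and its pseudogenes, or between a gene and its antisense partner can be lost or assigned to either, which can affect ribosomal protein genes, pseudogenes and mitochondrial genes, among others.

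Library totals ran from 16617885 to 20831599 counts. A total of 27680 features had 0 counts in all libraries. A count of 0 over the 108405728 counts of all libraries allows up to 0.0277 CPM (3 counts), and at the depth of a library 3 counts are 0.144 to 0.181 CPM. These floors cover counting error only, because reads without molecular identifiers are not independent molecules. Between libraries of a group, chi-square per degree of freedom over genes with a summed count of at least 20 ran from 4.28 to 17.3, so no pair agreed within sampling noise and each library was counted as a replicate.

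Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM composition factors, the default expression filter by group, robust quasi-likelihood fit and F test with group as the only term) and Benjamini-Hochberg adjustment over 16210 genes at 0.05. Standard errors of log2 fold changes were taken as the size of the fold change over the square root of F. CPM values in comparisons are TMM-normalised, and those of markers described over all 6 libraries use library totals. "Rose" and "fell" are used of genes past this test. ACSS2 was also tested by an exact two-sided permutation of log2 CPM. A total of 45 gene lists were written from textbook membership before the data were examined, as were the design, most alternatives and the rule for named genes. Of these lists 44 had at least 5 measured members and were tested with camera of limma 3.58.1 on voom values, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives.

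The genes named are ACSS2, ACSS1, ACSS3 and NUS1, and the 12 largest rises and 12 largest falls among genes past the test with a mean of at least 5 CPM and no overlap of the groups. The rule adds the 5 genes with the smallest p in each direction. From each list it adds up to 4 members past the test with a mean of at least 1 CPM and the largest change, or up to 2 with the smallest p where none passed. The rule's clause on biotype was not applied, because the table gives none. Of the list members that meet the rule, those that bear most on a comparison are described. Some genes that meet the rule are not reported here.

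For each gene, the longest annotated 3′ UTR among its protein-coding GENCODE v29 basic transcripts was taken. Whether these cells express that form was not examined, so a gene said to hold a sequence may lack it in its expressed form. Log2 fold changes of 13262 genes with a 3′ UTR of at least 50 bases were regressed on the presence of each of the 16384 possible 7-base sequences, adjusted for UTR length and GC content, and compared with 100 permutations of the fold changes. This search was chosen after the gene results were seen. It used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

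The alternatives were other scalings (RLE, upper quartile, library totals), no count filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 and voom in place of edgeR, an adjusted p of 0.01, omission of mitochondrially encoded genes, omission of each library in turn, and the replicate number as a block. Added after the data were seen were corrections for GC content and exon length, protein-coding genes alone and omission of genes with the shared 3′ UTR sequence. On simulated counts for NS against shACSS2 over 15957 genes, the test recovered 84% of genes changed 1.5-fold and 100% of those changed 2-, 3- or 4-fold, and 8.14% of the called genes were unchanged ones. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery below that level was not simulated. The simulated libraries carried no trend with GC content. With no gene changed, 0 of 15923 were called. Of the gene lists, 1 was shifted and camera called that list and no other. The simulated genes varied independently of each other, so calls of lists with correlated members were not tested by it. For the 3′ UTR search, 5 of 5 planted sequences were found.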

Results

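The series asked how a shortage of ACSS2 changes the transcriptome of human cells that the labels give as BE(2)-C, a cell line derived from a neuroblastoma. ACSS2 is the nuclear and cytosolic acetyl-CoA synthetase, which makes acetyl-CoA from acetate. Cells stably carrying a lentiviral short hairpin RNA against ACSS2 (shACSS2, n = 3 libraries) were set against cells carrying a non-silencing hairpin (NS, n = 3 libraries) by RNA sequencing. Library totals were 17073662, 18897496 and 20831599 counts in NS and 16617885, 16851285 and 18133801 counts in shACSS2. Between 22960 and 24903 of the 58735 annotated features had a count in a library, and 16210 genes were tested. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

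The targeted gene was far lower in the shACSS2 libraries. ACSS2 (ENSG00000131069, chromosome 20, 34872146 to 34927962, plus strand, GRCh38 coordinates) stood at 366, 387 and 438 counts in NS and at 75, 84 and 110 counts in shACSS2. Its normalised level fell from 20.5 ± 0.324 CPM (SD, n = 3) to 5.32 ± 0.762 CPM (SD, n = 3). The log2 fold change was −1.94 (a fitted fold of 0.261; SE 0.145; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.95e-06). An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest value that 3 against 3 libraries allow. The relatives of ACSS2 did not pass the test. Mitochondrial ACSS1 had a log2 fold change of −0.17 (SE 0.113; edgeR adjusted p = 0.311) and ACSS3 one of −0.26 (SE 0.146; edgeR adjusted p = 0.237). NUS1, which encodes the Nogo-B receptor that the treatment text names in passing for the established lines, had a log2 fold change of −0.05 (SE 0.11; edgeR adjusted p = 0.814).

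**Figure D1:**
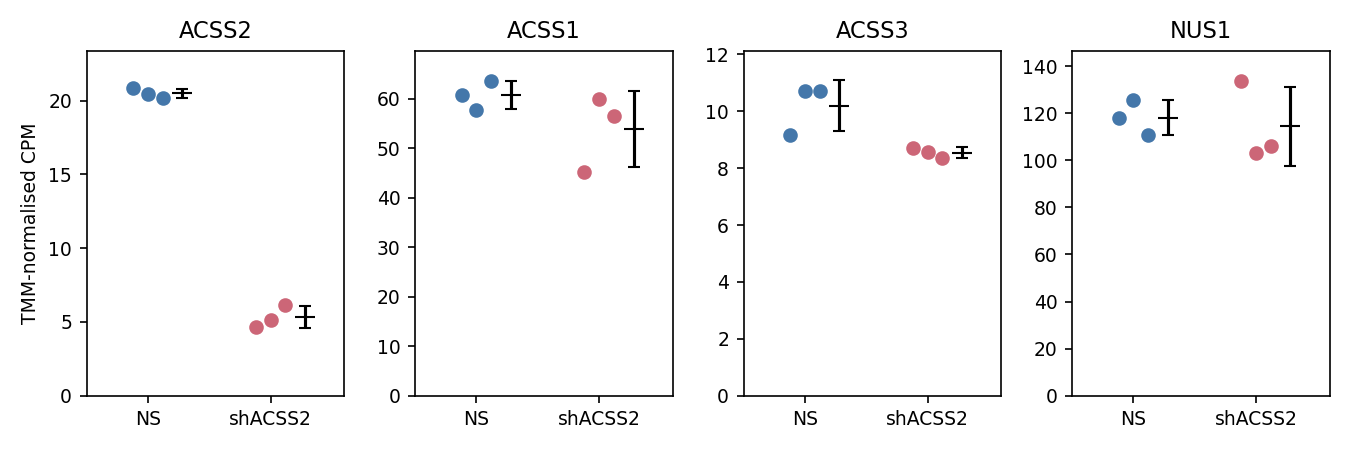
Normalised CPM of ACSS2, ACSS1, ACSS3 and NUS1 in each library, with 3 points per group and the mean ± SD drawn beside them. The shACSS2 libraries lie at 5.32 ± 0.762 CPM for ACSS2 against 20.5 ± 0.324 CPM in NS, while NUS1 overlaps between the groups.

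Several marker genes of adrenergic neuroblastoma were scarce or undetected in all 6 libraries. MYCN, the oncogene amplified in many neuroblastomas, had 0.421 to 2.12 CPM before composition factors, with a mean of 1.28 ± 0.62 (SD, n = 6). PHOX2A, TFAP2B and SOX11, transcription factors of the sympathoadrenal lineage, had 0 counts in every library, as had TH, the rate-limiting enzyme of catecholamine synthesis. With 108405728 counts in all, 0 counts allow a level of up to 0.0277 CPM (3 counts over the 6 libraries, counting error only). DBH, the enzyme that makes noradrenaline from dopamine, had at most 0.527 CPM. MYC, the paralog of MYCN, was abundant at 239 ± 22.8 CPM (SD, n = 6), and DDX1, a neighbour of MYCN in the genome, stood at 241 ± 22.5 CPM (SD, n = 6). IRS4, an insulin receptor substrate, reached 635 ± 67.2 CPM (SD, n = 6). These genes were singled out after their values were seen. Of 25 adrenergic neuroblastoma transcription factors listed before that, 14 had a mean of at least 5 CPM and 4 had no counts, with NS levels of 41.2 ± 0.221 CPM for GATA2, 24.4 ± 0.256 CPM for HAND1 and 13.0 ± 1.05 CPM for ISL1 (SD, n = 3 each). Every comparison that follows is between libraries labelled BE(2)-C.

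Across the transcriptome, 2776 of 16210 genes passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, 1213 higher and 1563 lower in shACSS2. Changes were mostly small, with 55 genes at least 2-fold higher and 262 at least 2-fold lower. These counts were 33 and 148 without NS replicate 1, and 40 and 152 without NS replicate 3. The share of higher genes among those called was 43.7%. With library totals in place of composition factors it was 25.8% (734 higher, 2108 lower), so the balance of directions depended on the scaling. In 36.3% of tested genes the CPM of the groups did not overlap, where chance gives 10%. The first principal component held 46.1% of the variance and separated the groups, and the second held 20.2% and set shACSS2 replicate 1 (score −30) apart from shACSS2 replicates 2 and 3 (23.8 and 14.2). Across genes, the deviation of shACSS2 replicate 1 from its group mean correlated with GC content with a Spearman coefficient of −0.6, against 0.47 and 0.39 in shACSS2 replicates 2 and 3. The number of genes called was 1018 without NS replicate 1, 1151 without NS replicate 3 and 3931 without shACSS2 replicate 1. Of the 174 named genes other than ACSS2, 68 were no longer past the test without NS replicate 1 and 62 without NS replicate 3.

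The genes that fell with the most certainty encode proteins of varied function. CASP2 (chromosome 7, 143288215 to 143307696, GRCh38), an initiator caspase, fell from 99.6 ± 6.16 to 36.9 ± 1.26 CPM (SD, n = 3 each; log2 fold change −1.43, SE 0.0987; edgeR adjusted p = 1.95e-06). RHOQ (chromosome 2, 46541806 to 46583121), a small GTPase, fell from 52.4 ± 1.09 to 19.1 ± 1.51 CPM (log2 fold change −1.46, SE 0.108). CREB3L2, a transcription factor anchored in the ER membrane, and COPZ1, a coatomer subunit, had log2 fold changes of −1.34 (SE 0.0972) and −1.15 (SE 0.0932). After ACSS2, the largest falls among genes with a mean of at least 5 CPM included AP3B2, a subunit of the neuronal AP-3 adaptor, at −1.51 (SE 0.155). N4BP2 stood at −1.47 (SE 0.137), PLGRKT, a plasminogen receptor, at −1.43 (SE 0.146), NHSL2 at −1.41 (SE 0.143) and SCART1 at −1.40 (SE 0.249). The noncoding RNA LINC00894 fell by 1.38 on the log2 scale (SE 0.23), but it is annotated as antisense and the strand setting of the counting is not given in the sources used here. MT-ND4L, MT-ND5 and MT-ND4 complete the 12 largest falls.

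**Figure D2:**
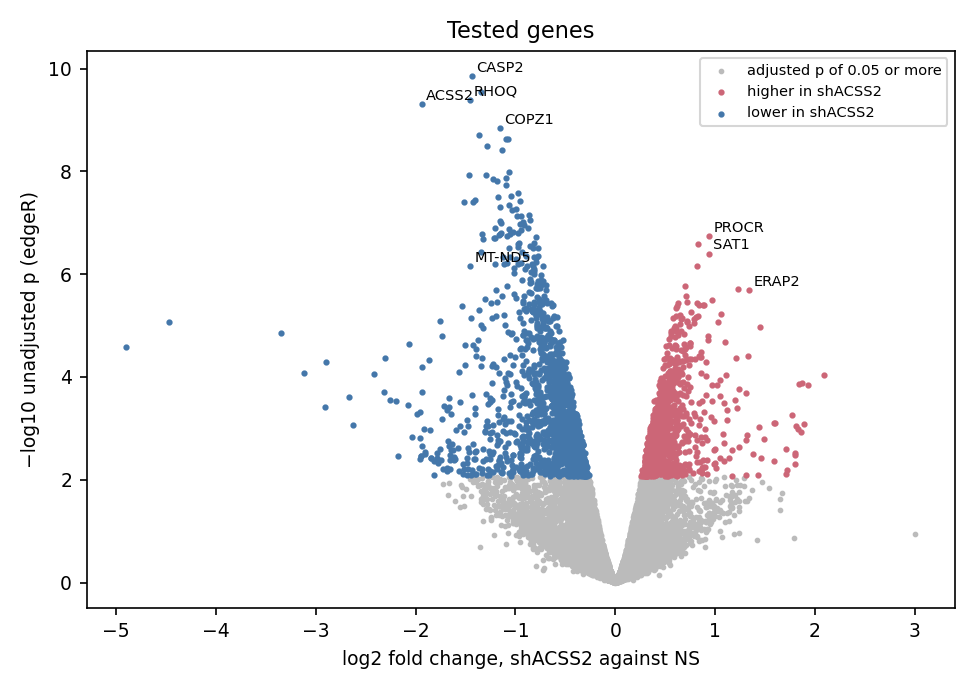
Log2 fold change of shACSS2 against NS (x axis) and −log10 of the unadjusted edgeR p (y axis) for the tested genes except 1 that is not drawn, coloured by direction where the adjusted p was under 0.05. Labels mark 8 of the named genes, among them ACSS2 and CASP2 on the lower side and PROCR and SAT1 on the higher side.

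Many of the genes that fell share a short sequence in their annotated 3′ UTR. Of the 1312 genes that fell and had a 3′ UTR of at least 50 bases, 576 (43.9%) held ATGCTCA or TGCTCAA there, as did 50 of the 128 (39.1%) that fell at least 2-fold. The share was 6.75% among the 1111 genes that rose and 16.0% among the 10839 not past the test. The sequence was picked from these same fold changes as the one with the lowest t, so these shares are a description and no test. CASP2, RHOQ, CREB3L2, COPZ1, AP3B2, N4BP2, PLGRKT and NHSL2 all held the sequence. In the 12 largest falls it was present in 6 of the 8 genes with an annotated 3′ UTR, and in the 12 largest rises in 0 of 10. The median log2 fold change was 0.07 in genes with no TGCTCA, −0.02 with TGCTCA alone, −0.15 with ATGCTCA or TGCTCAA and −0.26 with ATGCTCAA. Genes with the longer matches also had longer 3′ UTRs, with medians of 898, 2358, 3028 and 3704 bases in that order. Without all genes that held the sequence, the count of changed genes was 1844, with 834 higher, 1010 lower and 205 at least 2-fold lower (262 with them), an alternative chosen after the data were seen.

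**Figure D3:**
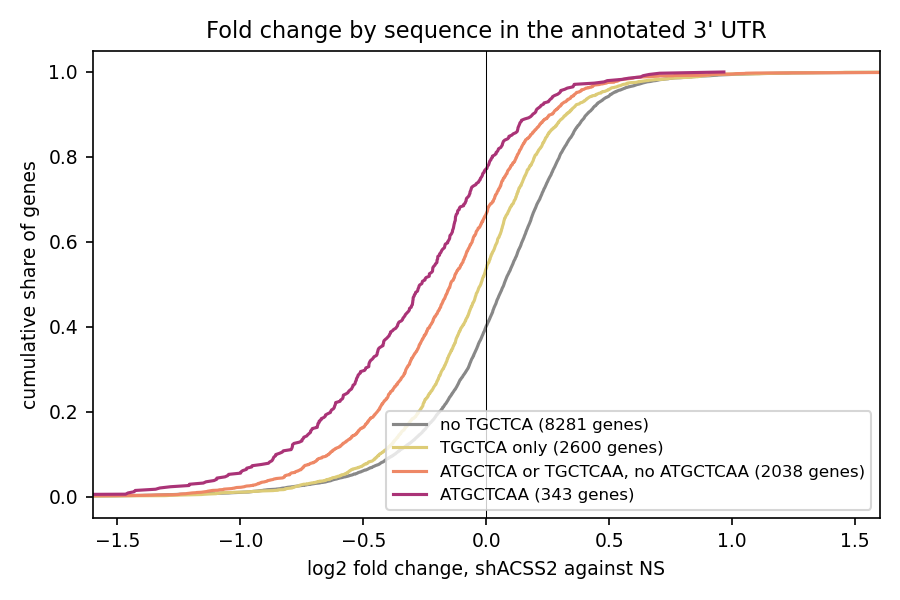
Cumulative share of genes (y axis) against the log2 fold change of shACSS2 over NS (x axis), by the longest match to ATGCTCAA in the annotated 3′ UTR. The curves shift to lower values from no TGCTCA (median 0.07) to ATGCTCAA (median −0.26).

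Among genes with a mean of at least 5 CPM, the 12 largest rises had log2 fold changes from 0.92 to 1.34. ERAP2 (chromosome 5, 96875939 to 96919716, GRCh38), an ER aminopeptidase that trims peptides for MHC class I, rose from 5.15 ± 0.826 to 13.1 ± 2.79 CPM (SD, n = 3 each; log2 fold change 1.34, SE 0.185; edgeR adjusted p = 0.000287). SERPINI1, which encodes neuroserpin, rose from 4.42 ± 0.467 to 10.4 ± 1.17 CPM (log2 fold change 1.23, SE 0.169; edgeR adjusted p = 0.000283). The other rises of this rank were SNCG (gamma-synuclein) at a log2 fold change of 1.06 (SE 0.16), MTLN (a mitochondrial micropeptide) at 1.03 (SE 0.16) and PON2 (a paraoxonase) at 0.97 (SE 0.139). SULT2B1, a sterol sulfotransferase, PROCR, the protein C receptor, and KLF15 rose by 0.96 (SE 0.194), 0.94 (SE 0.108) and 0.93 (SE 0.155). SAT1, which acetylates polyamines with acetyl-CoA, rose by 0.93 (SE 0.113), and SPHK1, a sphingosine kinase, by 0.92 (SE 0.152). Among the rises with the smallest p were also RAB29 at 0.83 (SE 0.0976), NR6A1 at 0.82 (SE 0.104) and JPT1 at 0.70 (SE 0.0954). The processed pseudogenes AL139095.2 (1.12, SE 0.266) and TWF1P1 (1.10, SE 0.184) also met the rule, and their values are uncertain because they can share reads with their parent genes. AL139095.2 lost the call without NS replicate 1, NS replicate 3 or shACSS2 replicate 2, with log2 fold changes of 1.06, 1.09 and 0.71 (edgeR adjusted p = 0.0534, 0.0508 and 0.0581).

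Transcripts of the mitochondrial genome were lower in shACSS2 for each of the 13 protein-coding genes. MT-ND5, a subunit of complex I, fell from 1094 ± 319 to 399 ± 18.4 CPM (SD, n = 3 each; log2 fold change −1.46, SE 0.168; edgeR adjusted p = 0.000133). MT-ND4L, MT-ND4 and MT-ND6 had log2 fold changes of −1.57 (SE 0.229), −1.45 (SE 0.187) and −1.33 (SE 0.183). The median of the 13 was −1.16, all 13 were also lower when adjusted over the list alone, and medians under the other scalings ran from −1.23 to −1.15 (camera adjusted p = 9.73e-16, and adjusted p = 0.541 with an estimated correlation). All genes of the mitochondrial chromosome together, of which 22 were tested, took 1.77 ± 0.48% of the counts in NS (SD, n = 3) and 0.740 ± 0.0429% in shACSS2 (SD, n = 3), and NS libraries ranged from 1.25% to 2.20%. Without shACSS2 replicate 1 the calls of MT-ND4L, MT-ND5, MT-ND4 and MT-ND6 ended, at edgeR adjusted p of 0.0898, 0.0503, 0.0515 and 0.0805 and log2 fold changes of −1.50, −1.45, −1.35 and −1.25. With the replicate block and the GC and length correction, chosen after the data were seen, the calls of MT-ND4L, MT-ND4 and MT-ND6 also ended, at edgeR adjusted p of 0.114, 0.0793 and 0.0852 and log2 fold changes of −1.55, −1.52 and −1.36. Nuclear copies of mitochondrial sequence and the overlap of MT-ND4L with MT-ND4 leave single values uncertain.

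The nuclear genes of the respiratory chain did not fall with them. In the oxidative phosphorylation list, 2 of 32 measured members rose, 1 fell and 29 did not pass the test, with 0 past it when adjusted over the list alone. Its median log2 fold change was 0.15 (camera adjusted p = 0.00125, and adjusted p = 0.702 with an estimated correlation). COX5A and NDUFB10 had log2 fold changes of 0.35 (SE 0.108) and 0.33 (SE 0.0953), and NDUFS1, whose 3′ UTR holds the shared sequence, one of −0.30 (SE 0.0948). Without NS replicate 3 the list's call ended (camera adjusted p = 0.107). The edgeR calls of those 3 genes each ended without NS replicate 1, NS replicate 3 or shACSS2 replicate 2, at adjusted p from 0.0963 to 0.184, those of COX5A and NDUFB10 also with library totals (0.0626 and 0.056) and that of NDUFS1 also without NS replicate 2 or shACSS2 replicate 3 (0.0831 and 0.164). The gene length correction, chosen after the data were seen, ended all 3 calls (edgeR adjusted p = 0.0694, 0.0525 and 0.223) and moved NDUFS1 to −0.17. COX5A also lost its call without the genes holding the shared sequence, at a log2 fold change of 0.33 (edgeR adjusted p = 0.055). The list's median was 0.08 with library totals, 0.09 without NS replicate 3, 0.25 without NS replicate 2 and 0.23 without shACSS2 replicate 3.

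Of 42 ribosomal protein genes, 36 rose, 0 fell and 6 did not pass the test, and all 42 rose when adjusted over the list alone. RPL35 rose from 1216 ± 202 to 1803 ± 144 CPM (SD, n = 3 each; log2 fold change 0.57, SE 0.115) and RPS9 had a log2 fold change of 0.50 (SE 0.0964). The list's median was 0.40, and 0.33 to 0.41 under the other scalings (camera adjusted p = 5.01e-21, and adjusted p = 0.568 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes that can share their reads. In the list of MYC and MYCN targets, 9 of 30 members rose, 0 fell and 21 did not pass the test, with 13 higher when adjusted over the list alone. ODC1, the rate-limiting enzyme of polyamine synthesis, rose from 420 ± 28.8 to 650 ± 18.6 CPM (log2 fold change 0.63, SE 0.0908). NOP56, a nucleolar protein of ribosome assembly, and ID2 had log2 fold changes of 0.54 (SE 0.0889) and 0.52 (SE 0.0912). The median was 0.25 (camera adjusted p = 2.43e-07, and adjusted p = 0.541 with an estimated correlation). For polyamine and nucleotide synthesis, 7 of 23 rose, 0 fell and 16 did not pass the test (10 higher adjusted over the list alone), among them CTPS1, which makes CTP, at 0.46 (SE 0.0972). The median was 0.18 (camera adjusted p = 0.000133, and adjusted p = 0.541 with an estimated correlation), and 0.11 with library totals.

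In the unfolded protein response of the ER, 12 of 20 members rose, 1 fell and 7 did not pass the test, with 14 higher and 2 lower when adjusted over the list alone. SDF2L1, an ER chaperone cofactor, rose from 35.4 ± 5.7 to 61.1 ± 4.85 CPM (SD, n = 3 each; log2 fold change 0.79, SE 0.123) and CALR, the chaperone calreticulin, from 635 ± 75 to 1003 ± 58.8 CPM (log2 fold change 0.66, SE 0.101). SEL1L, an adaptor of ER-associated degradation whose 3′ UTR holds the shared sequence, fell by 0.68 on the log2 scale (SE 0.125). The median was 0.43 (camera adjusted p = 3.26e-06, and adjusted p = 0.541 with an estimated correlation). For dolichol synthesis and N-glycosylation, 7 of 23 rose, 0 fell and 16 did not pass the test, with 8 higher adjusted over the list alone. ALG1, a mannosyltransferase, had a log2 fold change of 0.60 (SE 0.125) and STT3B, a catalytic subunit of oligosaccharyltransferase, one of 0.41 (SE 0.103). The edgeR call of STT3B ended without NS replicate 1 or NS replicate 3, at adjusted p of 0.0698 and 0.0614. The median was 0.26 (camera adjusted p = 0.000954, and adjusted p = 0.642 with an estimated correlation), 0.17 without NS replicate 3 and 0.10 without shACSS2 replicate 1. Among immediate early genes, 6 of 22 rose, 0 fell and 16 did not pass the test (7 higher adjusted over the list alone), led by DUSP1 at 0.68 (SE 0.126) and ATF3 at 0.66 (SE 0.127). Their median was 0.33 (camera adjusted p = 0.00124, and adjusted p = 0.612 with an estimated correlation).

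**Figure D4:**
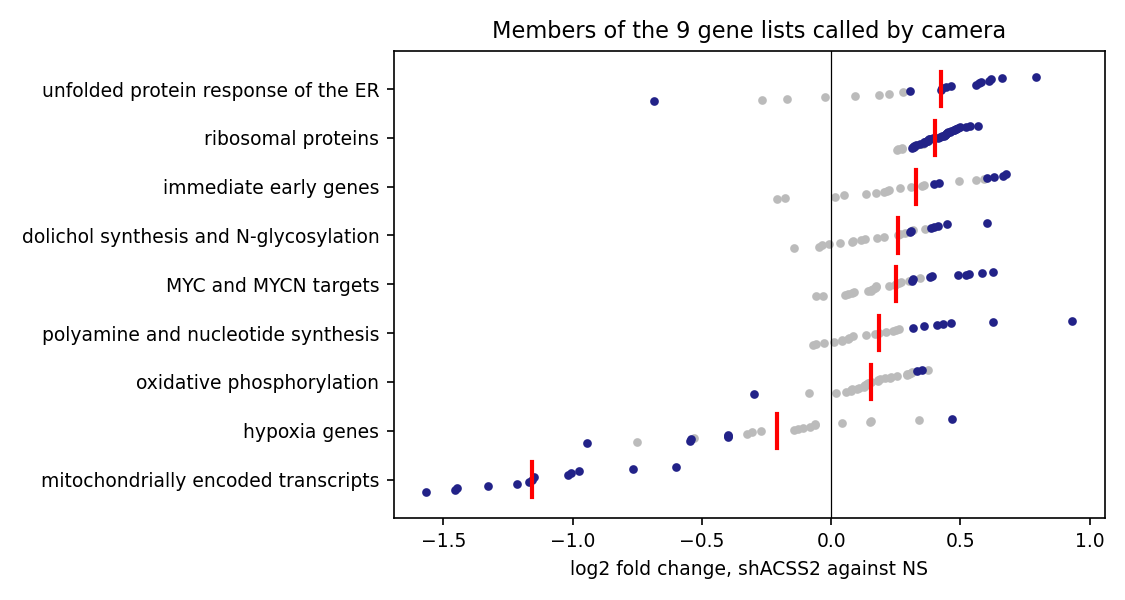
Log2 fold change of shACSS2 over NS for each measured member (points) of the 9 gene lists called by camera at the preset correlation of 0.01, with dark points past the edgeR test, grey points not past it and red bars at the median. Ribosomal protein genes cluster around a median of 0.40 and mitochondrially encoded transcripts around −1.16.

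Hypoxia genes leaned lower. Of 22 measured members, 1 rose, 6 fell and 15 did not pass the test, with 2 higher and 10 lower when adjusted over the list alone. LOX, a collagen crosslinking enzyme, fell from 114 ± 13.4 to 59.5 ± 3.48 CPM (SD, n = 3 each; log2 fold change −0.94, SE 0.106), and PDK1, a kinase that restrains pyruvate dehydrogenase, had a log2 fold change of −0.55 (SE 0.102). Both hold the shared 3′ UTR sequence, as do 7 of the 22 members. VEGFA, without it, had a log2 fold change of −0.54 (SE 0.117). The median was −0.21 (camera adjusted p = 0.0124, and adjusted p = 0.701 with an estimated correlation), and the call ended without NS replicate 3, without shACSS2 replicate 1 and without the genes that hold the sequence, at medians of −0.15, −0.18 and −0.14 and camera adjusted p of 0.116, 0.0587 and 0.19. None of the 9 calls by camera held with an estimated correlation, where 0 of 44 lists were called, and fry called 11 lists as moving on balance in 1 direction. Fry called 5 of the 9 and 6 others, and did not call oxidative phosphorylation, hypoxia, immediate early or dolichol and N-glycosylation genes (fry adjusted p = 0.307, 0.129, 0.0885 and 0.125). The 6 others, none called by camera, were p53 targets, G1/S genes, the interferon response and antigen presentation (higher; fry adjusted p = 0.0231, 0.0261, 0.0231 and 0.0376) and serine and folate metabolism and MAPK feedback genes (lower; fry adjusted p = 0.0299 and 0.0231).

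Lists of acetyl-CoA and lipid metabolism were not called by camera, and 17.1% of all tested genes were past the test as background for their counts. In acetyl-CoA supply, 1 of 24 rose, 3 fell and 20 did not pass the test (0 higher and 3 lower adjusted over the list alone), and the median log2 fold change was −0.03 (camera adjusted p = 0.372). The fallen members were ACSS2 itself, PDK1 and PDK4, another pyruvate dehydrogenase kinase, at −0.79 (SE 0.172). Fatty acid synthesis had 4 higher, 3 lower and 14 not past the test of 21 (4 and 4 adjusted over the list alone), with a median of 0.02, a mean of −0.02 and a camera direction of down (adjusted p = 0.929). SCD, the stearoyl-CoA desaturase, fell from 900 ± 43.3 to 598 ± 44.1 CPM (log2 fold change −0.59, SE 0.0928) and holds the shared sequence, while ME1, the cytosolic malic enzyme that makes NADPH, rose by 0.50 (SE 0.11). Fatty acid oxidation had 0 higher, 4 lower and 18 not past the test of 22 (1 and 4 adjusted over the list alone), with a median of 0.02, a mean of −0.07 and a camera direction of down (adjusted p = 0.929). Its regulator PPARA, with the shared sequence, had a log2 fold change of −0.86 (SE 0.113). In cholesterol synthesis 1 rose, 1 fell and 22 did not pass the test of 24 (1 and 1 adjusted over the list alone; camera adjusted p = 0.429). HMGCS1 had a log2 fold change of −0.48 (SE 0.115), with the edgeR call ending without NS replicate 1 at adjusted p = 0.0503.

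In the tricarboxylic acid cycle 4 members rose, 2 fell and 17 did not pass the test of 23 (4 and 2 adjusted over the list alone; camera adjusted p = 0.37), with IDH3G, a subunit of isocitrate dehydrogenase, at 0.55 (SE 0.0984) and PCK2, the mitochondrial PEP carboxykinase, at −0.61 (SE 0.118). Glycolysis had 0 higher, 2 lower and 19 not past the test of 21 (0 and 0 adjusted over the list alone; camera adjusted p = 0.414). For serine and folate metabolism, 0 of 16 rose, 6 fell and 10 did not pass the test (1 and 6 adjusted over the list alone; camera adjusted p = 0.14, fry adjusted p = 0.0299). SLC1A4, a neutral amino acid transporter, fell from 23.1 ± 1.11 to 11.6 ± 2.08 CPM (log2 fold change −0.99, SE 0.141) and ALDH1L2, of mitochondrial folate metabolism, by 0.70 on the log2 scale (SE 0.112), and both hold the shared sequence.

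Chromatin acetylation genes included several that fell. Of 28 histone acetyltransferases and deacetylases, 1 rose, 7 fell and 20 did not pass the test (4 higher and 8 lower adjusted over the list alone), with a median of −0.02 (camera adjusted p = 0.326). KAT2B, an acetyltransferase with the shared 3′ UTR sequence, fell from 22.5 ± 1.36 to 11.1 ± 1.34 CPM (SD, n = 3 each; log2 fold change −1.01, SE 0.132). Without that sequence, KAT6B had a log2 fold change of −0.81 (SE 0.104; −0.48 with the gene length correction and −0.49 with GC and length), HDAC6, a cytoplasmic deacetylase, of −0.60 (SE 0.124) and EP300, the p300 acetyltransferase, of −0.52 (SE 0.0958). All 10 measured replication-dependent histone genes failed to pass the test (0 adjusted over the list alone; camera adjusted p = 0.321).

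Apart from the ER unfolded protein response and hypoxia lists described above, the stress, cell cycle and apoptosis lists were not called by camera. Each of them had members past the test in both directions. The integrated stress response had 5 higher, 3 lower and 12 not past the test of 20 (7 and 4 adjusted over the list alone; camera adjusted p = 0.328), with ATF3 higher and DDIT4, an inhibitor of mTORC1, at −0.59 (SE 0.126). In the heat shock response 3 rose, 1 fell and 10 did not pass the test of 14 (4 and 1 adjusted over the list alone; camera adjusted p = 0.113), and DNAJA1, with the shared sequence, stood at −0.81 (SE 0.0997). Of 18 NRF2 and iron antioxidant genes 3 rose, 1 fell and 14 did not pass the test (3 and 1 adjusted over the list alone; camera adjusted p = 0.109), with HMOX1, the heme oxygenase, at 0.89 (SE 0.13) and GPX4, which reduces lipid peroxides, at 0.59 (SE 0.0938). Among p53 targets 4 rose, 1 fell and 15 did not pass the test of 20 (5 and 2 adjusted over the list alone; camera adjusted p = 0.0779, fry adjusted p = 0.0231), with AEN at 0.56 (SE 0.0909). G1/S genes counted 5 higher, 2 lower and 21 not past the test of 28 (7 and 2 adjusted over the list alone; camera adjusted p = 0.16, fry adjusted p = 0.0261), and G2/M genes 2, 4 and 22 of 28 (2 and 5 adjusted over the list alone; camera adjusted p = 0.321). HMMR, a spindle protein with the shared sequence, fell by 1.09 on the log2 scale (SE 0.105), and CENPE, a kinetochore motor without it, by 0.74 (SE 0.123). Apoptosis regulators had 4 higher, 2 lower and 16 not past the test of 22 (4 and 3 adjusted over the list alone; camera adjusted p = 0.414), with PMAIP1, which encodes NOXA, at 0.70 (SE 0.121).

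Neuronal and neuroblastoma lists were tested on the members that could be measured. Measured were 20 of 25 adrenergic neuroblastoma transcription factors, with 3 higher, 2 lower and 15 not past the test (3 and 3 adjusted over the list alone), and median, mean and camera direction were 0.07, −0.04 and up (adjusted p = 0.741). HAND1 had a log2 fold change of 0.62 (SE 0.111). MYCN stood at 1.75 ± 0.313 CPM in NS and 0.787 ± 0.308 CPM in shACSS2 (SD, n = 3 each; log2 fold change −1.14, SE 0.37; edgeR adjusted p = 0.0448). That call ended without any of the 6 libraries, at edgeR adjusted p from 0.0565 (without shACSS2 replicate 3) to 0.131 (without NS replicate 2). The 29 mesenchymal neuroblastoma genes had 2 higher, 6 lower and 21 not past the test (2 and 6 adjusted over the list alone; camera adjusted p = 0.398), among them SOX9 at −0.89 (SE 0.186) and YAP1, with the shared sequence, at −0.79 (SE 0.0991). Of 20 genes of catecholamine synthesis and storage 13 were measured, with 0 higher, 3 lower and 10 not past the test (1 and 3 adjusted over the list alone; camera adjusted p = 0.414). The granins CHGA, at 1.92 ± 0.318 CPM in NS, and SCG3 had log2 fold changes of −1.68 (SE 0.381) and −1.04 (SE 0.17). In neuronal differentiation 1 rose, 6 fell and 12 did not pass the test of 19 (1 and 8 adjusted over the list alone; camera adjusted p = 0.122), with SYP, the synaptic vesicle protein synaptophysin, falling from 41.1 ± 1.16 to 22.1 ± 4.4 CPM. Axon guidance counted 1 higher, 6 lower and 24 not past the test of 31 (2 and 9 adjusted over the list alone; camera adjusted p = 0.109), and 13 of the 31 hold the shared sequence.

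Of 16 immune cell markers 1 was measured, CD8A, and it did not pass the test (log2 fold change 0.52, SE 0.236; edgeR adjusted p = 0.136, and 1 higher adjusted over the list alone). All 7 measured Schwann cell and glial markers were not past the test (0 adjusted over the list alone; camera adjusted p = 0.414). MBP, which encodes myelin basic protein, had a log2 fold change of 0.25 (SE 0.143; edgeR adjusted p = 0.232) and passed the test under the length correction, the GC and length correction and the latter with the replicate block, all chosen after the data were seen, at 0.47, 0.48 and 0.48 (edgeR adjusted p = 0.0322, 0.0131 and 0.0105). Fibroblast and matrix markers had 1 higher, 1 lower and 10 not past the test of 12 (1 and 1 adjusted over the list alone; camera adjusted p = 0.398), where LUM, a matrix proteoglycan, rose from 2.14 ± 0.395 to 5.82 ± 1.12 CPM and COL5A1 fell by 0.50 on the log2 scale (SE 0.108). Endothelial and epithelial markers had 1 higher, 0 lower and 4 not past the test of 5 (2 and 0 adjusted over the list alone; camera adjusted p = 0.321).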

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

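The corrections for GC content and length, the restriction to protein-coding genes and the omission of genes with the shared 3′ UTR sequence were chosen after the data were seen. ACSS2 stayed lower and past the test under all 21 alternatives, with log2 fold changes from −2.06 to −1.85 and a largest adjusted p of 4.29e-05. No result reversed, and results below the threshold in both settings were scored as the same without regard to sign. The 2776 genes changed became 4288 with the GC and length correction and 4449 with the replicate block beside it, 1844 without genes holding the 3′ UTR sequence, 1842 without those and the mitochondrial genes (fewer genes tested), and 1010 at an adjusted p of 0.01. Leaving out 1 library gave 1018 (NS replicate 1) to 3931 (shACSS2 replicate 1), with 1151 without NS replicate 3. Of these, 1004 of the 1018 and 1132 of the 1151 were among the 2776. Genes higher numbered 1213, and 734 with library totals, 2149 with the GC and length correction, 2276 with the block beside it and 310 (without NS replicate 1) to 1837 (without shACSS2 replicate 1), with 363 without NS replicate 3 and 801 without shACSS2 replicate 2. Genes lower numbered 1563, and 1010 without genes holding the sequence, 1007 without those and the mitochondrial genes, and 708 (without NS replicate 1) to 2094, with 788 without NS replicate 3. Genes changed at least 2-fold numbered 317, and 194 among protein-coding genes, and 181 (without NS replicate 1) to 375, with 192 without NS replicate 3. The 9 lists called became 17 without a count filter and 0 with an estimated correlation, and 8 to 10 when a library was left out. Fewer samples or genes entered several of these fits, and otherwise the cause was not tested. Among named genes, 3260 results were the same, 296 lost the call and 3 gained it. Among single lists 879 were the same, 18 lost and 23 gained it. Replicate numbers showed no clear pairing of the samples, though 3 libraries per group leave little room to detect one. Deviations of same-numbered libraries from their group means correlated at −0.043, −0.066 and 0.11. By Spearman correlation of log2 CPM, NS replicate 1 was closer to shACSS2 replicate 3 than to its own number (0.9861 against 0.9809). So was NS replicate 2 (0.9888 against 0.9872), while NS replicate 3 correlated best with its own number (0.9851). With the replicate block 2923 genes were called. Loess corrections with lengths or biotypes from the table were not run, because it gives neither. Depth limits genes near 0.144 to 0.181 CPM, the value of 3 counts in a library.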

Other observations

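The tests of the share of 2-fold falls with the 3′ UTR sequence, of a joint fall of nuclear and mitochondrial genes, of handling, of a missing neuroblastoma program and of HEK293 genes were chosen only after the result was seen. So were the held-out check of the 3′ UTR sequence and the search for ATGCTCAAT in ACSS2.

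None of the signalling, immune, matrix and lysosome lists described next was called by camera, and 17.1% of all tested genes were past the test as background for their counts. In the Notch pathway 4 of 20 rose, 3 fell and 13 did not pass the test (4 and 3 adjusted over the list alone; camera adjusted p = 0.414). RBPJ, the DNA-binding mediator of Notch, fell from 138 ± 6.61 to 78.5 ± 5.26 CPM (SD, n = 3 each) and holds the shared 3′ UTR sequence, while HEY2, a Notch target, rose by 0.68 on the log2 scale (SE 0.14). Hippo pathway targets had 2 higher, 4 lower and 10 not past the test of 16 (2 and 4 adjusted over the list alone; camera adjusted p = 0.328), with CRIM1 at −0.79 (SE 0.107). Wnt pathway targets had 1, 3 and 16 of 20 (1 and 3 adjusted over the list alone), with a median of 0.05, a mean of 0.04 and a camera direction of down (adjusted p = 0.825), and WNT5A stood at −0.56 (SE 0.102). TGF-beta and BMP targets had 4, 2 and 13 of 19 (4 and 2 adjusted over the list alone; camera adjusted p = 0.414), with ID3 at 0.53 (SE 0.102) and SKIL at −0.63 (SE 0.117). MAPK feedback genes had 0, 3 and 11 of 14 (0 and 3; camera adjusted p = 0.328, fry adjusted p = 0.0231), with CCND1, which encodes cyclin D1, at −0.46 (SE 0.0929). The retinoic acid response had 2, 1 and 11 of 14 (2 and 2; camera adjusted p = 0.91) and NF-kB targets 1, 1 and 8 of 10 (1 and 1; camera adjusted p = 0.627).

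Antigen presentation genes had 5 higher, 0 lower and 12 not past the test of 17 (5 and 0 adjusted over the list alone; camera adjusted p = 0.119, fry adjusted p = 0.0376). B2M, the light chain of MHC class I, rose from 173 ± 23 to 275 ± 34.8 CPM (SD, n = 3 each), and its longest annotated 3′ UTR holds the shared sequence. The interferon response had 3, 1 and 16 of 20 (3 and 1; camera adjusted p = 0.214, fry adjusted p = 0.0231), with IFI44L rising from 0.809 ± 0.557 to 3.56 ± 0.747 CPM, and it too holds the sequence. Matrix remodelling and adhesion genes had 3, 2 and 20 of 25 (5 and 3; camera adjusted p = 0.328), where PLAU, the urokinase, rose by 1.33 (SE 0.236) and LAMB1, a laminin chain, fell by 0.84 on the log2 scale (SE 0.105). For autophagy and lysosome 5 rose, 4 fell and 20 did not pass the test of 29 (7 and 4; camera adjusted p = 0.414), with GLA, a lysosomal hydrolase, at 0.59 (SE 0.0931) and LAMP1, which holds the sequence, at −0.63 (SE 0.0959).

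Many genes fell by about 2-fold with little spread between replicates, and for a part of them a candidate explanation is seed pairing of a short RNA present in the shACSS2 cells. Of 16384 7-base sequences, ATGCTCA had the lowest t (−18.11, with a lowest of −5.06 over 100 permutations), and in each of 9 pairs of 1 shACSS2 and 1 NS library it was also the lowest, with t from −20.1 to −17.7 in the remaining libraries, which had no part in picking it. Seed pairing is argued against as the account of most genes that fell at least 2-fold. Of the 128 such genes with a searched 3′ UTR, 50 held ATGCTCA or TGCTCAA (39.1%, SE 4.31). Those genes were taken by fold size alone, without regard to spread. Of the 30 fallen genes with the lowest edgeR p and a searched 3′ UTR, 26 (86.7%) held either sequence, so there the share goes the other way. The sequence was picked from these same fold changes, so the latter share is a description. Whether that RNA may be the guide of the ACSS2 hairpin stays open. The reagent's sequence is not given in the sources used here, and the titles name an siRNA where the text describes a hairpin. The test written for it beforehand was the occurrence in ACSS2 of the 8-base extension with the lowest t (AATGCTCA, slope −0.23, SE 0.0172). That test gave 0 of 24 annotated transcripts, the outcome set beforehand as speaking against the guide. Ranking by t may have been a poor bound, as it favours common sequences, but this reservation was not part of the prediction. AATGCTCA was held by 482 genes and ATGCTCAA by 343, and the slope of ATGCTCAA (−0.25, SE 0.0203) differed from that of AATGCTCA by less than their SEs. ATGCTCAAT, joined from the 7-base sequences with the lowest t and also no part of the prediction, lies in 8 ACSS2 transcripts. It lies in the coding part of exon 15 (chromosome 20, 34925751 to 34925759, plus strand, GRCh38). Of all possible 9-base sequences, 2.04% occur somewhere in ACSS2 transcripts. CATGCTCA, in the same number of transcripts as ATGCTCAAT, had a weaker slope of −0.12.

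Mitochondrially encoded transcripts were lower in shACSS2, and a joint fall of nuclear and mitochondrial respiratory genes is argued against by the nuclear list. Its median log2 fold change was 0.154 (SE 0.0251 from resampling its members, which leaves out the spread between libraries). Over 19 alternatives that median ran from 0.083 to 0.247. Less carry-over of RNA without poly(A) tails could not be decided, as 2 RNAs of the list written for it were measured (median 0.164). Such carry-over could account only for mitochondrial transcripts that lack these tails, and tails were not examined here. The 10 histone genes, whose mRNAs mostly lack poly(A) tails, had a median of −0.31 with none past the test (edgeR; camera adjusted p = 0.321). Handling that differed between RNA preparations may contribute, since the highest NS share was 1.76 times the lowest against 2.39 times between the groups, and the labels give no batch. An effect of ACSS2 loss itself was not tested apart from these.

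Neuroblastoma marker genes were near or at 0 in libraries labelled BE(2)-C, with 10 of 10 core markers under 3 CPM in every library, but these were picked after low values were seen. Whether the cells carry no MYCN-amplified adrenergic neuroblastoma program stays open, as 14 of 25 adrenergic factors listed beforehand had a mean of at least 5 CPM. Loss of reads to overlapping genes is argued against, because 10 of the 10 had under 50% of their exonic bases in exons of other genes. A further hypothesis is that the cells may be HEK293 or a line derived from it, since 6 of 6 genes known from HEK293 were above 5 CPM, with IRS4 at 635, NEFM at 135, NEFL at 107, INA at 83.2, LHX1 at 10.6 and PAX2 at 8.36 CPM. This cannot be told apart from other origins, because no reference profile was used here and NEFL, NEFM and INA, 3 of the 6, are also expressed in neuronal cells.

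The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2776 genes and 1 of 10 splits reached that, with 1 gene as the highest other. Every other split mixes NS and shACSS2, which puts the group difference into the spread within groups. Low gene counts there follow from that and are no measure of chance. At least 2-fold changes numbered 317 in the real split and 1 in the highest other, so 1 of 10 splits was as large. For gene lists the real split called 9, the highest other 12, and 5 of 10 splits called as many, so calls by camera at the preset correlation arise in groupings that mix NS and shACSS2. Those groupings are uneven mixtures that keep a part of the group difference, so their calls are not all false ones by design.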
